A study of Mus musculus with 1 sample.

How the data were processed

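The data were 1 expression array of cultured mouse oligodendrocyte progenitor cells. These are the dividing precursors of the oligodendrocytes that myelinate axons in the central nervous system. Per the labels' protocols, total RNA was extracted on columns and 150 ng of it was turned into biotin-labelled sense-strand target for an Affymetrix whole-transcript array, whose probes lie along the length of each transcript. Per the submitters' processing notes, the values were made with RMA in Affymetrix Expression Console, with no version recorded. RMA corrects each array for background, sets all arrays normalised together to the same distribution of intensities, and summarises the probes of each set. The deposited values were taken as log2 RMA levels. The file does not name the scale, and this reading rests on the method and on the range of the values, from 3.26 to 14.4. Which arrays were normalised together is not given in the sources used here, so the shape of this array's distribution may carry that of other arrays. The genome build behind the probe sets is not given in the sources used here, and no coordinates are reported.

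The study's design text describes 6 samples, in which fibroblasts, with or without lentiviral transcription factors, were set against progenitor cells. Only the progenitor array was analysed here; the fibroblast arrays were not. No difference between samples, no replicate error and no p-value could therefore be computed, and every value below is the level of 1 gene on 1 array with no error attached. The sample's title, description and source name call it oligodendrocyte progenitor cells, whereas its cell type characteristic reads MEFs, the abbreviation of mouse embryonic fibroblasts, with no treatment. The group was taken from the title.

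The array held 35556 probe sets. GEO's platform annotation gave exactly 1 gene symbol to 21789 of them and several to 1621; the other 12146 were unnamed in that table. Of the probe sets with 1 symbol, 21698 carried a gene identifier found in the reference gene table of assembly GRCm38.p6, which was used for names only. Probe sets with several genes named none. Probe sets of the same gene were averaged on the log2 scale, which gave 19938 genes, of which 999 had several probe sets. Among these 999, the probe sets of 195 genes differed by more than 2 log2 units.

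Background was estimated from the array itself. Olfactory and vomeronasal receptors are used in sensory neurons of the nose, and their 1205 probe sets (1035 olfactory and 170 vomeronasal) were taken as probe sets without their own transcript. Their median was 5.29, and the 95th percentile of their levels, 7.20 on the log2 scale, was the background limit. By construction 5% of these receptor probe sets lie above it. A stricter limit of 8.58, chosen after seeing the data, was the highest level among 19 measured genes of hepatocytes and skeletal muscle, 8 of which lay above the first limit. On a simulated array of 19938 genes, background was drawn from the same receptor levels that set the limit. A share near 5% for genes with no added signal was therefore fixed by construction, and it was 4.22%. Of genes raised by 1 log2 unit, 8% lay above the limit, as did 52% of those raised by 2. The share was 90% for a rise of 3, and all genes raised by 4 passed, with 50 genes per size. These shares hold only for genes whose background is like that of the receptors.

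The 31 gene lists were each summarised as the number of measured members above each limit, and as its median level with that median's percentile among 10000 random lists of the same size drawn from all genes. The 95% interval of a median came from order statistics. It bounds the median and does not cover the range of the members. It treats members as a random draw, which chosen lists are not, and members are not replicates. Levels of different probe sets also reflect probe affinity. The order of probe set levels, and a list's percentile, therefore describe brightness on this array and not the order of transcript abundance. The lists, the first limit and the rule for named genes were fixed before the data were examined. The rule named the first 4 measured members of each list in their written order, every measured transcription factor of the oligodendroglial list, up to 4 members on the opposite side of the limit from the list's majority, and the 10 probe sets with the highest levels; other genes named were chosen after their values were seen, and the text says so. Of 419 distinct genes in the lists 393 were measured, and 3 older symbols were updated. Alternatives were a 99th percentile limit, olfactory or vomeronasal receptors alone, the median of all probe sets with 1 gene as the limit, the highest probe set of a gene, probe sets of several genes kept, random lists, but not the fixed lists, limited to genes above background, and medians without dim members. A limit from the array's own control probe sets was planned and not run, because the annotation used does not mark them. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.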

Results

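Gene expression was measured on 1 array of mouse oligodendrocyte progenitor cells, the reference cell type against which the study set fibroblasts infected with inducible transcription factors. Of 19938 genes, 13498 (67.7%) lay above the background limit of 7.20 and 7835 (39.3%) above the stricter limit of 8.58, which was chosen after seeing the data. The median gene level was 8.04. With 1 array there was no replicate, so no level carries an error and no difference was tested. The labels disagree on what the sample is: its title names progenitors and its cell type characteristic names fibroblasts. The comparison of reprogrammed with untreated fibroblasts was not analysed here.

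The first question was whether the array carried the profile of progenitors, and all 18 measured members of the progenitor list lay above background, 16 of them above the stricter limit. Pdgfra, the receptor for the mitogen PDGF-AA, was at 12.23. Cspg4, which encodes the NG2 proteoglycan of progenitors, was at 9.92. The lineage transcription factors Olig2 and Sox10 were at 11.20 and 10.02. Of the 18, 10 also stand in other lists below. The median of the list was 10.29 (95% interval over genes 9.24 to 11.82), at percentile 99.99 among random lists of 18 genes.

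Among 15 measured oligodendroglial transcription factors, several of which can drive or mark this lineage, 13 lay above background and 9 above the stricter limit. Olig1 was at 13.07, Sox9 at 11.61, Sox8 at 10.84, Sox6 at 10.41, Tcf7l2 at 10.23, Nkx2-2 at 10.18 and Sox5 at 8.89, beside Olig2 and Sox10 above. Nkx6-2 at 8.44, Nkx6-1 at 8.34, Myt1 at 8.27 and Myrf, a regulator of myelin genes, at 7.73 lay between the 2 limits. St18 at 6.42 and Zfp536 at 6.63 lay below background. The list's median of 10.02 stood at percentile 99.92. Of the 15, 9 also stand in other lists. Olig1, Olig2, Sox10, Nkx2-2 and Sox6 are members of the progenitor list, so the percentiles of these lists are not separate results.

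Markers of later stages of the lineage were set against the same limits. Of 12 genes of committed, premyelinating cells, 10 lay above background and 7 above the stricter limit, with Bcas1 at 9.11 and the calcium channel gene Itpr2 at 9.04. Bmp4 at 7.03 and Enpp6 at 6.25, both known from newly formed oligodendrocytes, lay below background. Of 18 genes of mature myelinating cells, 12 lay above background and 3 above the stricter limit. Of all genes on the array, 67.7% and 39.3% did so, and the first count does not set the list apart. The myelin protein genes Mbp at 7.60 and Mobp at 7.64 lay between the 2 limits. So did the unrelated tissue genes Apoa2 at 7.94 and Acta1 at 8.54, and these levels do not separate Mbp and Mobp from probe background. Mog at 7.18, Mag at 7.14, Opalin at 6.21 and Aspa at 6.30 lay below the background limit. The 3 genes above the stricter limit, named after their values were seen, were Gjc3 at 12.05, Cnp at 10.12 and Ugt8a at 9.57. The list medians were 8.82 (95% interval 7.78 to 10.23; percentile 87.6) for premyelinating and 7.57 (7.14 to 7.89; percentile 19.4) for mature cells.

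Fibroblast genes were examined because the cell type characteristic names fibroblasts. Of 20 genes, 14 lay above background and 3 above the stricter limit, against 67.7% and 39.3% of all genes. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 were at 8.96, 8.31 and 8.39. Dcn at 6.33, Lum at 6.24, Postn at 6.26 and Fap at 6.14 lay below background. Fn1 at 9.46 and Col5a1 at 8.62 were the other two above the stricter limit, and were named after their values were seen. The list's median was 7.68 (95% interval 6.90 to 8.18), at percentile 24.1 among random lists. The skeletal muscle list, fixed as an unrelated tissue, had a median of 7.56 at percentile 24.9. The fibroblast percentile therefore does not set its list apart from genes taken as unused. Of 8 contractile genes of smooth muscle and myofibroblasts, with a median of 7.86 at percentile 40.3, 6 lay above background and 2 above the stricter limit. Acta2, the smooth muscle actin, was at 10.94, Tagln at 8.54, Cnn1 at 8.06 and Myh11 at 7.44, while Actg2 at 7.05 and Des at 6.69 lay below. Of 8 pericyte genes, with a median of 7.19 at percentile 13.2, 4 lay above background and 1 above the stricter limit. Among those above background were Pdgfrb at 7.62, Kcnj8 at 7.45 and Abcc9 at 7.23, while Rgs5 was at 6.53.

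**Figure D1:**
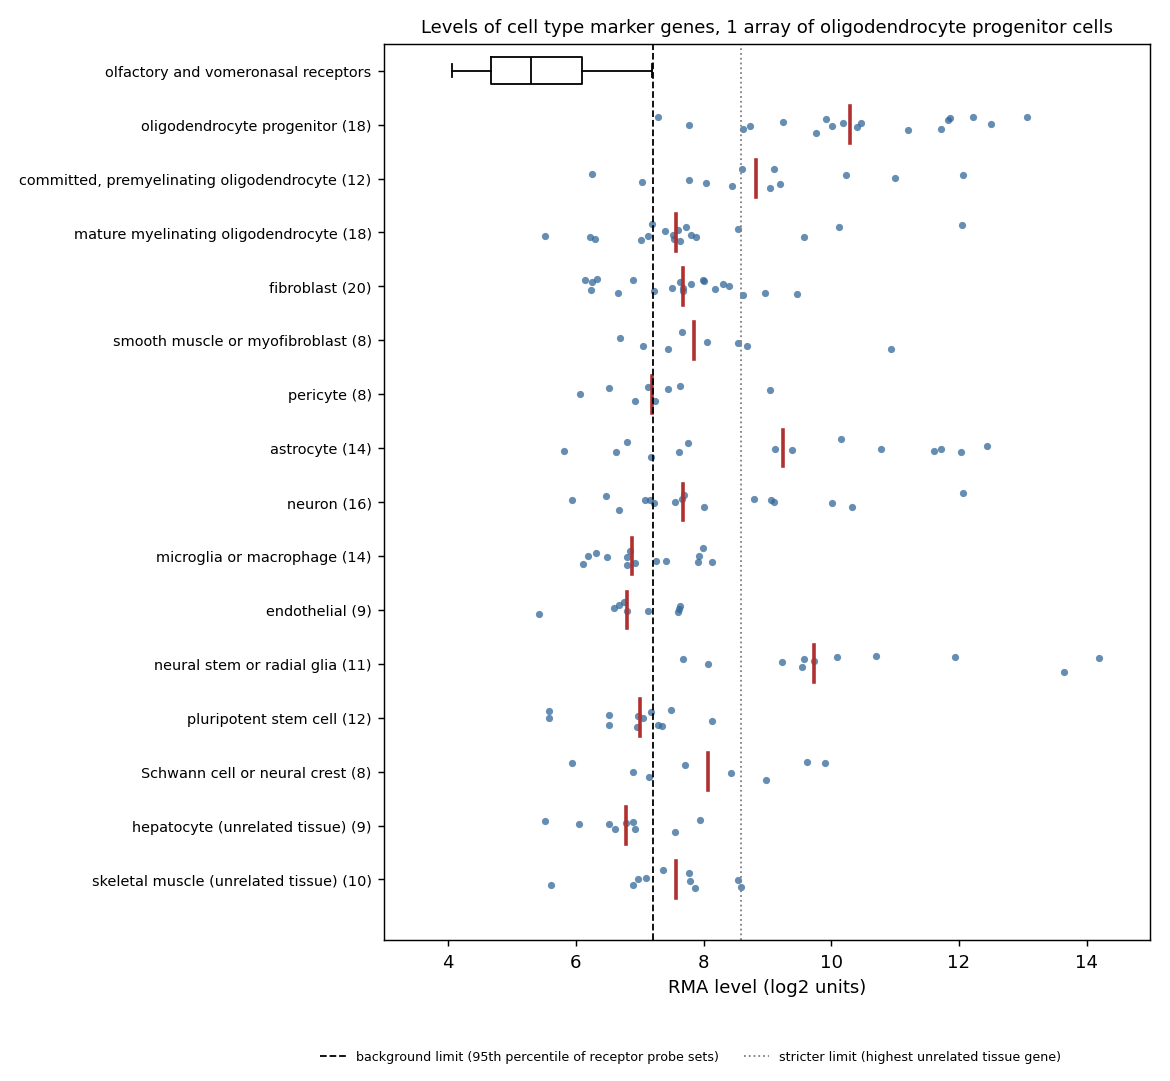
RMA level on a log2 scale (x axis) of each measured gene of the cell type lists (rows, number of genes in brackets). Points are genes on 1 array, red bars are list medians, and the box shows the receptor probe sets (median and quartiles, whiskers at the 5th and 95th percentiles). All 18 progenitor genes lie right of the dashed limit at 7.20, and 3 of 20 fibroblast genes lie right of the dotted limit at 8.58.

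Lists of other cell types that a culture of neural cells could hold gave different counts. All 11 neural stem and radial glia genes lay above background and 9 above the stricter limit, with Sox2 at 11.94, the intermediate filament gene Nes at 10.70, Sox1 at 9.23 and Pax6 at 8.06. The median of 9.73 stood at percentile 98.9. Of 14 astrocyte genes, 10 lay above background and 8 above the stricter limit, with a median of 9.25 at percentile 97.0; 2 of the 14 also stand in another list. The astrocyte filament gene Gfap at 7.17, the water channel gene Aqp4 at 6.63, Gjb6 at 5.82 and Cyp4f14 at 6.80 were the 4 below background, while the glutamate transporter gene Slc1a2 was at 9.11 and Aldh1l1 at 7.76. Aldoc at 12.44, Slc1a3 at 12.04 and Acsbg1 at 11.71 were also above the stricter limit, and were named after their values were seen. Of 16 neuronal genes, with a median of 7.68 at percentile 26.7, 11 lay above background and 6 above the stricter limit. For all genes on the array the shares were 67.7% and 39.3%. The synaptic genes Syt1 and Snap25 were at 10.01 and 9.10, Rbfox3 at 7.69 and Tubb3 at 7.55, and Stmn2 at 7.09, Nefl at 7.16, Slc17a6 at 6.46 and Gad2 at 5.94 lay below. Map2 at 12.06 and Dcx at 10.33 were above the stricter limit, and were named after their values were seen.

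No microglial, endothelial or pluripotency gene of the lists lay above the stricter limit. Of 14 microglial genes 6 lay above background, among them Trem2 at 8.13, Cx3cr1 at 7.99, Tyrobp at 7.41 and C1qa at 7.25, while Aif1 at 6.19, Csf1r at 6.80 and P2ry12 at 6.11 lay below. Of 9 endothelial genes 3 lay above background, Cldn5 at 7.63, Flt1 at 7.61 and Tie1 at 7.62, while Pecam1 was at 6.68 and Cdh5 at 7.13. Of 12 pluripotency genes 4 lay above background, Lin28a at 8.13, Fgf5 at 7.49, Esrrb at 7.35 and Utf1 at 7.29; Pou5f1, which encodes Oct4, was at 6.52, Nanog at 7.17 and Zfp42 at 5.58. The medians of the 3 lists stood at percentiles 2.60, 5.38 and 5.36. Of 8 Schwann cell and neural crest genes, 5 lay above background and 3 above the stricter limit, with Egr2 at 8.43 and Foxd3 at 7.71, and Pmp2 at 5.95, Tfap2a at 7.15 and Pax3 at 6.90 below. Of the unrelated tissue genes, 2 of 9 hepatocyte genes, Apoa1 at 7.55 and Apoa2 at 7.94, and 6 of 10 skeletal muscle genes, among them Acta1 at 8.54, lay above background. Alb at 6.04, Fgb at 6.61, Myh1 at 5.62, Myh2 at 6.97, Myh4 at 6.90 and Mylpf at 7.09 did not. The median was 6.79 at percentile 5.1 for the hepatocyte list and 7.56 at percentile 24.9 for the skeletal muscle list. The latter was close to the medians and percentiles of the fibroblast, mature oligodendrocyte and neuronal lists.

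Of 19 proliferation genes all lay above background and 18 above the stricter limit, with a median of 11.02 (95% interval 10.27 to 11.63) that was higher than the medians of all 10000 random lists. Mki67 was at 11.61, the mitotic kinase gene Cdk1 at 11.90 and the cyclin gene Ccna2 at 12.26. Top2a was at 7.92 as the mean of 2 probe sets that disagreed, at 11.19 and 4.64. All 11 measured inhibitors and genes of cell cycle exit lay above background and 8 above the stricter limit. Their median of 8.98 stood at percentile 89.5, and at 57.7 among random lists of genes above background. Cdkn1b, which encodes p27, was at 9.48 as the mean of 2 probe sets that disagreed, at 11.10 and 7.85. Cdkn1c was at 9.43, Cdkn2a at 8.48 and Cdkn2b at 7.94.

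The labels' protocols state that the progenitor medium held FGF2 and PDGF-AA. Receptors for these and other ligands, and target genes of FGF and ERK signalling, feedback genes among them, were examined. Of 16 receptor genes, most of them for other ligands, thyroid hormone included, 14 lay above background and 13 above the stricter limit. The median of 9.35 stood at percentile 98.65, and at 85.05 among random lists of genes above background. Fgfr1 was at 11.19, Fgfr3 at 9.38 and Fgfr2 at 8.86, beside Pdgfra above, while Met at 6.15 and the thyroid hormone receptor gene Thrb at 7.15 lay below background. All 14 FGF and ERK target genes lay above background and 11 above the stricter limit, with a median of 10.56 at percentile 99.99. Not all of them are feedback genes, and 1 of the 14 also stands in another list. The phosphatase gene Dusp6 was at 12.27, the Sprouty genes Spry4 and Spry2 at 11.48 and 10.67, and Etv4 at 9.29. Of 14 Notch pathway genes, 13 lay above background and 11 above the stricter limit. Notch1 was at 10.09, its targets Hes5 and Hes1 at 9.54 and 9.12 and its ligand Dll1 at 9.34, while Hey2 at 7.12 lay below background. The list's median of 9.39 stood at percentile 98.2, and at 85.3 among random lists of genes above background. Of 16 Wnt and BMP genes, 14 lay above background and 6 above the stricter limit. Tcf7l2 was at 10.23, Axin2 at 8.53 and Id1 at 8.36, with Lef1 at 6.86 and Bmp4 at 7.03 below; the median of 8.40 stood at percentile 71.9.

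**Figure D2:**
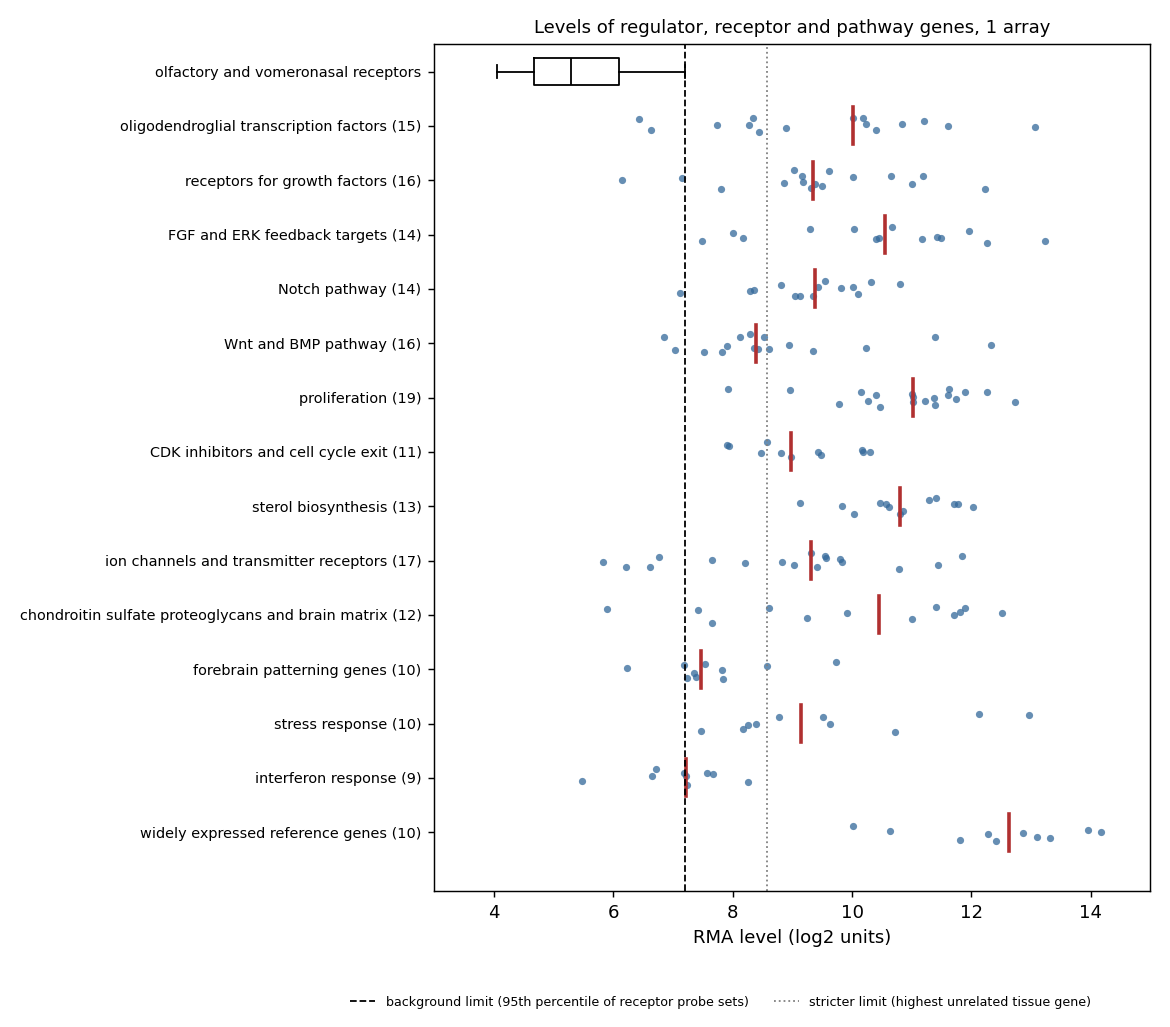
RMA level on a log2 scale (x axis) of each measured gene of the regulator, receptor and pathway lists (rows, number of genes in brackets) on 1 array. Red bars are list medians, the box shows the receptor probe sets as in the plot of cell types, and all 13 sterol and 18 of 19 proliferation genes lie right of the dotted limit at 8.58.

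All 13 measured genes of sterol biosynthesis lay above the stricter limit, with a median of 10.80 (95% interval 10.04 to 11.71) that was higher than those of all 10000 random lists. Hmgcs1, an early enzyme of the pathway, was at 12.03, Fdps at 11.71, Sqle at 11.29 and Idi1 at 10.86. Of 12 genes of proteoglycans and brain matrix, 11 lay above background and 9 above the stricter limit, with Ncan at 11.90, Bcan at 11.40 and Cspg5 at 11.00, and Hapln1 at 5.89 below. Of 17 ion channel and transmitter receptor genes, 13 lay above background and 11 above the stricter limit. The AMPA receptor subunit genes Gria3, Gria4 and Gria2 were at 11.44, 10.79 and 9.84, whereas Gria1 at 6.61 lay below background, as did Grin2a at 6.22, Scn3a at 5.82 and Scn2a at 6.77, the last as the mean of 14 probe sets that ran from 5.40 to 8.49, on both sides of the limit.

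Genes of position along the body axis were also read. The 37 Hox genes had a median of 7.34, at percentile 3.13 among random lists. Of them, 23 lay above background and 5 above the stricter limit, against 67.7% and 39.3% of all genes. The 5 were Hoxa2 at 9.25, Hoxa4 at 9.21, Hoxa5 at 9.01, Hoxb3 at 9.16 and Hoxb2 at 8.83; Hoxb3 and Hoxb2 were named after their values were seen. Hoxa3 was at 7.39, and Hoxa11 at 6.87, Hoxb6 at 6.87, Hoxc4 at 6.34 and Hoxc5 at 6.89 lay below background. Of the 14 genes in paralog groups 1 to 5, 9 lay above background and 5 above the stricter limit; of the 23 in groups 6 to 13, the counts were 14 and 0. At the 99th percentile limit of 8.33 they were 6 of 14 and 1 of 23. By cluster, 9 of 10 Hoxa, 8 of 9 Hoxb, 4 of 9 Hoxc and 2 of 9 Hoxd genes lay above background. The 10 forebrain patterning genes had a median of 7.47, at percentile 20.5 among random lists. Of them, 8 lay above background and 1 above the stricter limit, Lhx2 at 9.73, named after its value was seen. Emx1 was at 8.58, just under that limit, Dlx2 at 7.83 and Dlx1 at 7.54, while Emx2 at 7.19 and Otx2 at 6.24 lay below background.

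**Figure D3:**
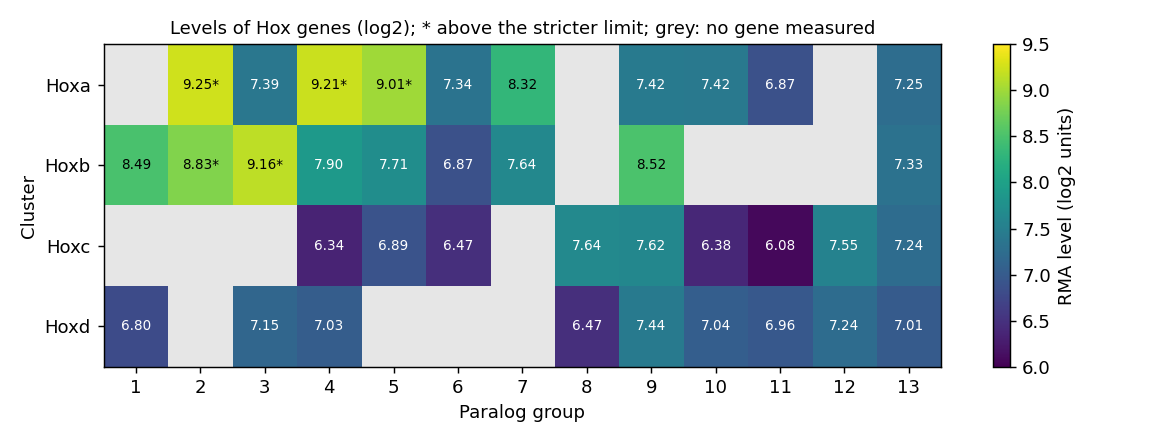
RMA level on a log2 scale (colour and printed value) of each measured Hox gene on 1 array, by cluster (rows) and paralog group (columns); grey cells have no measured gene. The 5 genes marked with an asterisk lie above the stricter limit of 8.58 and belong to the Hoxa and Hoxb clusters.

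All 10 measured stress genes lay above background and 6 above the stricter limit. The chaperone gene Hspa5 was at 12.97, Hspa1a at 8.78, Ddit3 at 8.40 and Atf3 at 7.46. The stress median of 9.15 stood at percentile 93.13, and at 69.75 among random lists of genes above background. Of 9 interferon-response genes 5 lay above background and none above the stricter limit; Oas1a was at 7.57 and Irf7 at 7.23, and Ifit1 at 6.72, Ifit3 at 6.65, Mx1 at 5.47 and Usp18 at 7.19 lay below. All 10 widely expressed reference genes lay above the stricter limit, with Eef1a1 at 14.17, Actb at 13.95, Rplp0 at 13.32 and Tubb5 at 13.11. The 10 probe sets with the highest levels among those with 1 gene were assigned to Rn7sk, Baiap2l1, Fabp7, Eef1a1, Ckb, Txn1, Kcnma1, Actb, H4c4 and Rpl10, at levels from 14.28 down to 13.77. For Baiap2l1 and Kcnma1, other probe sets of the same gene were as low as 6.70 and 9.19. Fabp7, a fatty acid binding protein of glial precursors, was at 14.20 and the brain creatine kinase gene Ckb at 14.14, each from 1 probe set.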

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

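With 1 array, leaving out replicates was not possible, and a higher limit can only lower a count. The limit was 8.33 at the 99th percentile of the receptor probe sets, 6.47 from vomeronasal and 7.23 from olfactory receptors alone, 8.08 at the median of all probe sets with 1 gene, 8.58 at the highest unrelated tissue gene and 9.06 at the 95th percentile of skin-restricted families; the last 2 were added after seeing the data. Against 13498 genes above background, the 99th percentile gave 8813, the unrelated tissue limit 7835 and the skin limit 6064. The 14 fibroblast genes fell to 4, 3 and 1 in that order, and to 6 at the median of all probe sets. The 12 mature oligodendrocyte genes fell to 4, 3 and 3, and to 4. The count of 10 premyelinating genes moved by more than 1.5 times at the skin limit alone, to 5. The progenitor count fell from 18 to 16 at the 99th percentile, the median and the unrelated tissue limit, and to 14 at the skin limit. It stayed within a factor of 1.5 of 18 under all 8 alternatives. All 18 measured members passed the first limit, so the settings that could only raise a count could not move it. When the random lists, but not the lists themselves, were limited to genes above background, percentiles could by construction fall but hardly rise: those of proliferation and reference genes stayed at 100, and those of the fibroblast and mature oligodendrocyte medians went to 0 and 0, that of premyelinating genes from 87.6 to 46.2 and that of Wnt and BMP genes from 71.9 to 12.8. Over all 31 lists, counts moved by more than 1.5 times in 14 lists at the 99th percentile, 13 at the median, 16 at the unrelated tissue limit and 19 at the skin limit, each time downward, in 6 upward with vomeronasal receptors and in 1 downward with olfactory receptors. Taking the highest probe set or keeping probe sets of several genes moved none of the 31 counts by that much, nor any median out of its 95% interval. Leaving out members below background moved 3 of the 31 medians out of that interval, all upward, and the limited random lists lowered 16 of the 31 percentiles beyond the range that interval gives. No error within a gene can be given. A gene simulated at 2 log2 units over background drawn from the receptor levels passed the limit in 52% of cases.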

Other observations

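The tests in this part were all chosen after the values they bear on had been seen. Xist, the RNA that coats the inactive X chromosome, was at 12.72, while the Y-linked genes Eif2s3y at 6.04, Kdm5d at 6.30 and Uty at 5.21 lay below the background limit. Among the 12146 probe sets with no gene named here, 5307 (43.7%) lay above background. Some of them may be control probe sets, which the annotation used does not mark, so the share is no count of transcripts. Of the 10 probe sets with 1 gene and the highest levels, those assigned to Baiap2l1 and Kcnma1 disagreed with other probe sets of the same gene. Baiap2l1 had 3 probe sets at 14.21, 12.17 and 6.70, and Kcnma1 had 2 at 14.00 and 9.19.

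The skeletal muscle and hepatocyte genes were fixed as genes that these cells would not use, yet 8 of 19 lay above the limit drawn from nose receptors. If receptor probe sets understate the background of other probe sets, other tissue-restricted families should pass the limit more often than the 5% of the receptors themselves. Of 76 probe sets of keratin-associated, late cornified envelope and small proline-rich protein genes, 21 lay above it. The exact 95% binomial interval takes probe sets as independent, which members of the same family may not be, so it may be too narrow. The share was 27.6% (interval 18.0 to 39.1). This is consistent with a background that differs between gene families, and probe base composition, for which no sequences were at hand, is an untested candidate cause. Low use of these genes in the cells stays open, and no biological explanation was tested.

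Fibroblast genes lay above the background limit in 14 of 20 cases, on a sample whose cell type characteristic names fibroblasts; of all genes on the array 67.7% lay above that limit, so the count does not set the list apart. Against the reading that the whole sample is untreated fibroblasts stand the lineage transcription factors Olig1, Olig2, Sox10 and Nkx2-2. Untreated fibroblasts are known to lack them, and all 4 lay above 9.06, the highest of the background limits tried. Olig1 at 13.07 and Olig2 at 11.20 also lay above the brightest receptor probe set, at 10.20. Sox10 at 10.02 and Nkx2-2 at 10.18 did not. Fibroblasts given transcription factor vectors, which the design text describes, were not covered by this check. Probe background may account for part of the 14, since 3 genes lay above the highest of the unrelated tissue genes and 1 above the skin limit. A share of fibroblasts or similar cells in the culture stays open: of 7 abundant fibroblast transcripts, 4 (Col1a1, Col1a2, Col3a1 and Fn1) lay above the limit and Dcn, Lum and Postn did not. These explanations cannot be told apart for these genes without a fibroblast array to give the level a given share would need.

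The Hox genes above the stricter limit of 8.58 belonged to paralog groups 2 to 5, but this split rests on a limit chosen after seeing the data. The genes above it were 5 of 14 in groups 1 to 5 and 0 of 23 in groups 6 to 13, against 9 of 14 and 14 of 23 at the first limit, 6 and 2 at the median of all probe sets with 1 gene, and 6 and 1 at the 99th percentile of the receptors. Hoxb9, named after its value was seen, lay just under 8.58 at 8.52. Probe background above the receptor limit cannot be told apart from use of these genes: 3 of the 5, Hoxa2 at 9.25, Hoxa4 at 9.21 and Hoxb3 at 9.16, also lay above the 95th percentile of the skin-restricted families at 9.06, and no probe sequences were at hand. No biological explanation was tested.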
